A study of Mus musculus with 4 samples.

How the data were processed

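The series measured T-cell receptors of single cells from pancreatic islets of NOD mice (non-obese diabetic, a strain that develops autoimmune diabetes spontaneously) and of NOD mice lacking Tet2, an enzyme that oxidises methylcytosine in DNA. Per the labels, 4 libraries were made, 2 from NOD and 2 from Tet2KO NOD islets, and the islets of 4 to 6 mice were pooled for each. The series' design text gives the mice as 10 to 13 weeks of age, while the labels' protocol counts the same weeks after an event abbreviated BTM. The labels also mention donors for bone marrow transplant among the NOD mice, so neither the age nor whether the islets came from transplanted mice was settled here, and the comparisons are by labelled genotype. The libraries of each genotype carry the set numbers 1 and 2. Pools of mice were the replicates, and the number of receptors from each mouse within a pool was not analysed here.

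The deposited values were whole-number counts of reads and of UMIs (unique molecular identifiers) for each assembled contig, with its chain, V and J segment, CDR3 sequence and flags, per the file headers. Cell Ranger 7.0.1 made the contigs, the cell calls and the clonotype numbers, per the submitters' processing notes, which name the build GRCm38 (mm10). The set of V(D)J segments it used is not given in the sources used here. Contig length in bases, also deposited by the authors, was not used in a test. A segment name is the closest match in that set, so near-identical copies (the D and N copies of TRAV segments) are uncertain, and NOD alleles can differ from the reference. The joined name TRBV12-2+TRBV13-2 was kept as deposited; its CDR1 and CDR2 were those of TRBV13-2 in 1379 contigs of called cells.

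A cell was a barcode the authors' files flag as a cell. Its chains were the high-confidence, full-length, productive TRA and TRB contigs. Paired cells had at least 1 TRA and 1 TRB. Cells with over 1 TRB were left out as possible doublets, and where a cell had over 1 TRA the chain with the most UMIs was used. A clonotype was an identical V segment, J segment and CDR3 nucleotide sequence of both chains. A clonotype in a pooled library can hold cells of several mice.

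Clonality was computed after each library was thinned to 1392 paired cells, the number in the smallest library, as the mean of 200 draws. Values were the share of cells in clonotypes of 2 or more cells, the share in the 10 largest clonotypes, Shannon entropy divided by the log2 of the number of cells, the inverse Simpson index and the number of clonotypes. The share in the largest clonotype used all cells. Each value was compared between genotypes with an exact two-sided permutation test over the 6 assignments of the 4 libraries, whose smallest possible p is 0.333, so no such test could pass 0.05. No p-value was made from cells.

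Segment usage was tested on the number of clonotypes with each V or J segment of TRA and TRB, counting each clonotype once, with edgeR 4.0.16 (quasi-likelihood test, R 4.3.3). The library size was the number of clonotypes, with no further normalization factor. Segments were kept with a count of at least 10 in at least 2 libraries, and p-values were adjusted by Benjamini-Hochberg over all 124 segments kept. The same test over 13 lists fixed before the data were examined used the lists as rows. Standard errors of log2 fold changes are approximate, from the fold change and its F statistic. On simulated data with 20 of 124 segments changed (50 simulations), this test recovered 19.6% of segments changed 1.5-fold, 66.7% of those changed 2-fold and 89.1% of those changed 3-fold, and 2.97% of the calls at 1.5-fold, 3.27% at 2-fold and 2.64% at 3-fold were false. Every segment was simulated at the fit's own common dispersion, 0.0023. These values therefore do not cover segments that vary more between pools.

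Named segments were chosen by a rule fixed before the data were examined: segments passing the test, up to 10; the 6 TRBV, 6 TRAV, 4 TRBJ and 4 TRAJ with the highest mean share; and the 5 higher and 5 lower with the smallest unadjusted p among those whose genotypes did not overlap. Every list was named, with the largest clonotype of each library and the 3 clonotypes with the most cells among those found in over 1 library. The lists were receptors of the invariant NKT type (TRAV11 family with TRAJ18) and of the MAIT type (TRAV1 with TRAJ33), TRAV16 family with TRAJ42, TRAV5D-4 or TRAV5-4, TRAV/DV segments, TRAJ58 to TRAJ40, TRAJ20 to TRAJ2, the TRBJ1 and TRBJ2 clusters, the TRBV13 family, TRBV19, TRBV2 and TRBV26. The name TRAV5D-4 did not occur among the paired cells, so its list rests on TRAV5-4.

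Sharing was counted for the 6 pairs of libraries. CDR3 beta amino acid sequences were compared after thinning to 899 clonotypes, and sharing within genotypes was set against sharing between them over the 3 ways to split 4 libraries into pairs (smallest p 0.333). Intervals are Wilson 95% intervals, and a count of 0 was taken to allow up to 3. Both cover counting error only. Locations are from GENCODE's mouse annotation of GRCm38, which held 123 of the 124 segment names tested.

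Alternatives planned before the data were examined were other clonotype definitions, other filters on cells and UMIs, other thinning, TMM factors, DESeq2 1.42.0, no filter on low counts, each cell counted once, the set number as a replicate block and leaving out each library. Those added after the data were seen left out clonotypes found in over 1 library, merged joined and duplicated segment names, crossed the set numbers, and left out cells whose barcode and TRB occurred in any contig, or in a contig of more reads, of another library. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene expression and chromatin libraries named in the series' design text were not used here, so the loss of Tet2 was not checked in these libraries.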

Results

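T-cell receptors were read in 4 libraries of pancreatic islet cells, 2 from pools of NOD mice and 2 from pools of Tet2KO NOD mice. The contig tables held 220516119, 140478435, 114106599 and 85137263 reads for NOD 1, NOD 2, Tet2KO NOD 1 and Tet2KO NOD 2. They gave 6835, 2889, 1957 and 1664 called T cells, of which 5564, 2475, 1604 and 1392 carried 1 TRB paired with a TRA. Reads in the contigs of called cells, per called cell, were lowest in NOD 1, at 27650, against 45005, 53630 and 46412 in the others. The median cell had 6 TRA UMIs in each library and 11, 13, 10 and 11 TRB UMIs, so receptor recovery per cell was close while the number of cells was not. Called cells averaged 4862 ± 2790 in NOD and 1810 ± 207 in Tet2KO NOD (SD, n = 2, exact permutation p = 0.333, the smallest possible). Cells with over 1 TRB made up 5.75% and 4.40% of the called cells of NOD and 3.37% and 3.97% of those of Tet2KO NOD.

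The first comparison asked how far islet T cells had expanded clonally in each genotype. At 1392 cells per library, 31.8% and 35.1% of NOD cells and 53.2% and 39.2% of Tet2KO NOD cells belonged to clonotypes of 2 or more cells. The means were 33.5% ± 2.34 and 46.2% ± 9.86 (SD, n = 2), a difference of 12.7 percentage points with both Tet2KO libraries above both NOD libraries. The exact permutation test gave p = 0.333, the smallest this design allows, so the difference was not established against the spread between pools. Its size rested largely on Tet2KO NOD 1: without that library the difference was 5.73 percentage points, and without Tet2KO NOD 2 it was 19.7. Without thinning the shares were 44.1% and 40.6% in NOD and 54.6% and 39.2% in Tet2KO NOD, which overlapped, with a difference of 4.52 points (n = 2, exact permutation p = 1). Within set 1 the difference was 21.3 points and within set 2 it was 4.08. At 1392 cells per library the number of clonotypes was 1049 ± 35.2 in NOD and 897 ± 136 in Tet2KO NOD (SD, n = 2, exact permutation p = 0.333). That difference of -152 was -56.0 without Tet2KO NOD 1 and -248 without Tet2KO NOD 2.

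**Figure D1:**
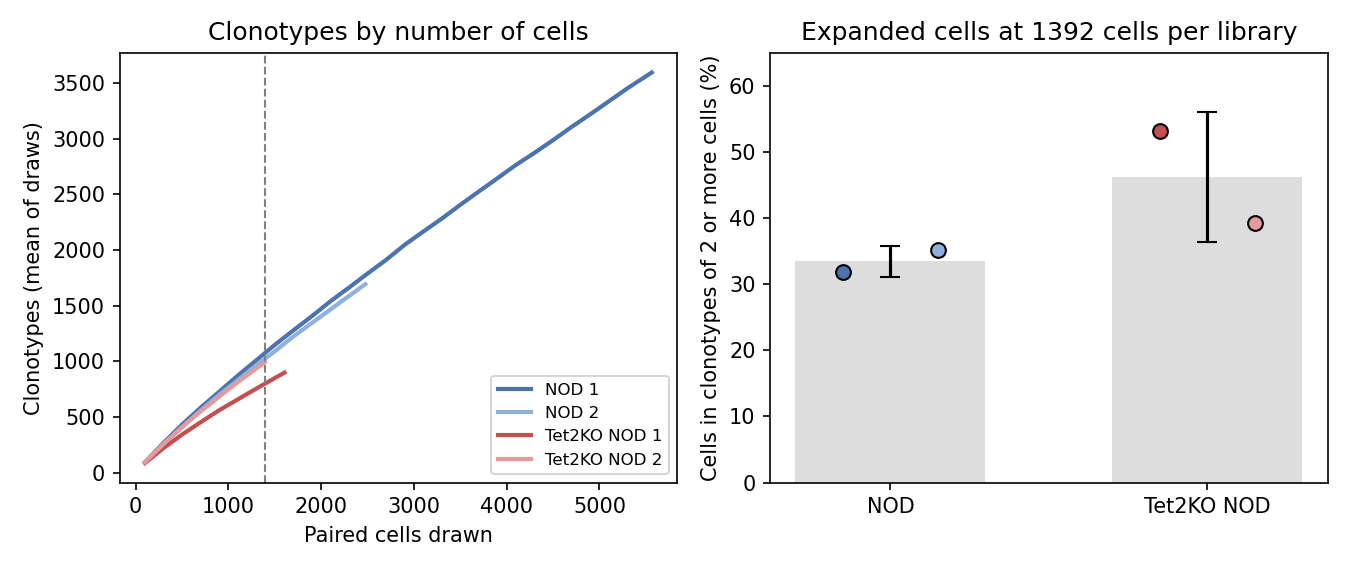
Left, clonotypes (vertical axis) against the number of paired cells drawn (horizontal axis), 1 line per library, with a dashed line at 1392 cells. Right, percent of cells in clonotypes of 2 or more cells at that depth, with points for libraries, bars for genotype means and error bars of 1 SD (n = 2); Tet2KO NOD 1 stands at 53.2% and the other 3 libraries between 31.8% and 39.2%.

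Measures of the largest clones overlapped between genotypes. The 10 largest clonotypes held 7.82% and 11.6% of the thinned NOD cells and 16.1% and 9.05% of the Tet2KO NOD cells, a difference of means of 2.88 points (n = 2, exact permutation p = 0.667) that became -0.66 without Tet2KO NOD 1. The inverse Simpson index, an effective number of equally large clonotypes, was 556 and 388 in NOD and 213 and 461 in Tet2KO NOD (exact permutation p = 0.667, n = 2). Normalized entropy averaged 0.925 ± 0.0137 and 0.884 ± 0.0456 (SD, n = 2, exact permutation p = 0.667). When each library was left out, the difference in inverse Simpson index ran from -258 to -10.7 and that in entropy from -0.0735 to -0.00894.

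The largest clonotype held 1.37% of cells in NOD 1 (76 cells, Wilson 95% interval 1.09% to 1.71%), 1.66% in NOD 2 (41 cells, 1.22% to 2.24%), 2.68% in Tet2KO NOD 1 (43 cells, 2.00% to 3.59%) and 1.58% in Tet2KO NOD 2 (22 cells, 1.05% to 2.38%). In NOD 1 it paired TRBV16 CDR3 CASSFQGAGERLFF with TRAV18 CDR3 CAGLTGSGGKLTL. A further 73 cells of that library carried the same TRB with TRAV5-4 CDR3 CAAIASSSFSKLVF. TRB alone joins them into 1 clone, and so do the deposited clonotype numbers. The share in NOD 1 thus depends on the clonotype definition used here, with 1 TRA kept per cell. Whether these cells carried both TRA was not tested. The genotype difference for paired clonotypes was 0.62 points, and ran from 0.0692 to 1.17 when each library was left out. With clones defined by TRB alone the largest held 2.68%, 2.22%, 2.99% and 1.58% of cells in the 4 libraries, a difference of -0.16 points. The deposited clonotype numbers gave the same difference, -0.16 points. The largest clonotype of NOD 2 paired TRBV31 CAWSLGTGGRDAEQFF with TRAV3-1 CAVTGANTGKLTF. Those of Tet2KO NOD 1 and 2 paired TRBV20 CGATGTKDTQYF with TRAV2 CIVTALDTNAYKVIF, and TRBV1 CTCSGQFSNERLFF with TRAV7D-4 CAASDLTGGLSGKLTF.

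The second comparison asked whether the genotypes used different receptor segments. TRBV2, the V beta 4 segment carried by the diabetogenic BDC2.5 receptor, had a smaller share in the Tet2KO NOD libraries. It made up 6.71% and 5.97% of NOD clonotypes and 4.67% and 3.52% of Tet2KO NOD clonotypes. Its log2 fold change was -0.66 (SE 0.18, adjusted p = 0.0363 by edgeR's quasi-likelihood test), and both Tet2KO libraries lay below both NOD libraries. That test pools its estimate of spread over segments (common dispersion 0.0023). Its p therefore rests mostly on all segments together and little on the spread of TRBV2 between pools. The exact permutation test of these shares gave p = 0.333 (n = 2), the smallest possible, so the difference was not established between pools. TRBV2 lies on chromosome 6 of GRCm38 from 41047340 to 41047995, on the plus strand. It was the 1 segment of 124 that passed, with 0 higher, and 5 segments had an unadjusted p below 0.05. Genotypes did not overlap for 32 segments (25.8%, against 33.3% by chance).

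The TRBV2 call passed in 3 of 15 alternatives, with adjusted p from 0.0132 to 0.997 by edgeR or DESeq2, though its fold change was negative in all 15. It was lost by edgeR when each cell was counted once (log2 fold change -0.34, adjusted p = 0.997) and by DESeq2 (-0.64, adjusted p = 0.991). The call was also lost by edgeR with the set number as a replicate block and with the sets crossed. Leaving out NOD 1 (log2 fold change -0.55), Tet2KO NOD 1 (-0.87) or Tet2KO NOD 2 (-0.46) lost it as well.

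The most used TRBV segments did not pass the test. The joined TRBV12-2+TRBV13-2 name averaged 11.3% ± 0.942 of NOD and 11.5% ± 1.55 of Tet2KO NOD clonotypes, TRBV5 10.4% ± 0.128 and 10.1% ± 0.863, TRBV19 9.12% ± 1.64 and 8.31% ± 1.21, and TRBV13-1 8.73% ± 0.321 and 8.14% ± 0.124 (SD, n = 2). TRBV16 averaged 6.67% and 7.20%, and TRBV1 6.49% and 6.98%. Among TRAV segments TRAV5-4 averaged 6.79% and 6.90%, TRAV16N 5.51% and 5.78%, TRAV6N-7 5.35% and 5.86%, TRAV13-1 4.30% and 4.05%, TRAV9-1 3.87% and 3.97%, and TRAV6D-6 3.54% and 3.40%. TRBJ2-7 was the most used TRBJ (21.3% and 19.8%), ahead of TRBJ2-5 (12.4% and 12.5%), TRBJ2-3 (10.8% and 11.9%) and TRBJ2-1 (10.5% and 9.89%). The most used TRAJ were TRAJ23 (4.65% and 4.99%), TRAJ40 (3.87% and 5.22%), TRAJ49 (4.84% and 4.18%) and TRAJ18 (4.19% and 4.29%). Adjusted p by edgeR was 0.849 for TRAJ40 and 0.992 for the others in this paragraph.

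**Figure D2:**
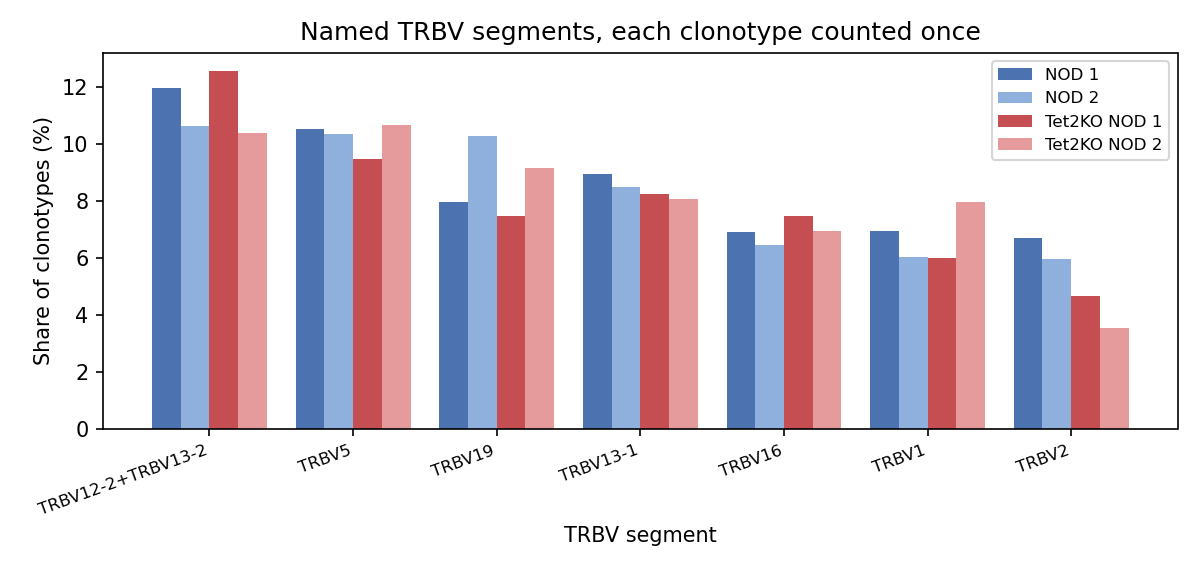
Share of clonotypes in percent (vertical axis) for the named TRBV segments (horizontal axis), each clonotype counted once, 1 bar per library. TRBV2 stands at 6.71% and 5.97% in NOD and at 4.67% and 3.52% in Tet2KO NOD.

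Other segments without overlap between genotypes failed the adjustment. Only the 5 with the smallest unadjusted p on each side, TRBV2 included, are given in this paragraph. On the higher side in Tet2KO NOD they were TRAJ40, TRAV1, TRAV5N-4, TRAV14D-3-DV8 and TRBJ2-4. Their log2 fold changes were 0.44 (unadjusted p = 0.0182 by edgeR), 1.05, 0.46, 0.84 and 0.23, in that order. Besides TRBV2, those on the lower side were TRAJ50 (-0.55, unadjusted p = 0.0275 by edgeR), TRAJ9 (-0.72), TRAJ13 (-0.57) and TRAV12-3 (-0.68). TRBV13-1, TRBV16, TRBJ2-3 and TRAJ49, given above, did not overlap between genotypes either. TRAV1 rested on 18, 14, 13 and 11 clonotypes. When each library was left out, the log2 fold change ran from -1.67 to -0.14 for TRAV12-3, -1.19 to -0.18 for TRAJ13, -0.84 to -0.32 for TRAJ50, 0.61 to 1.33 for TRAV1, 0.49 to 1.16 for TRAV14D-3-DV8 and 0.12 to 0.44 for TRBJ2-4.

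The lists fixed beforehand gave 1 call of 13. TRBV2 was lower (log2 fold change -0.67, adjusted p = 0.0225 by edgeR, adjusted over the lists alone). The adjusted p of the other 12 lay between 0.735 and 0.995 by the same test. The exact permutation test of the TRBV2 shares gave p = 0.333 (n = 2). The TRBV2 call is not a second result, since this list counts the same clonotypes as the TRBV2 segment. That call was lost, leaving 0 lists, when each cell was counted once, when cells with over 1 TRB were kept, and without NOD 1, NOD 2 or Tet2KO NOD 2. The TRBV13 family, the V beta 8 segments, made up 28.3% ± 0.652 of NOD and 27.4% ± 0.730 of Tet2KO NOD clonotypes (SD, n = 2). TRBV19, V beta 6, made up 9.12% and 8.31%. TRBV26, the V beta 3 segment subject to deletion by an endogenous superantigen in NOD mice, was rare in both, at 0.676% ± 0.130 and 0.837% ± 0.240. The list of TRAV5D-4, known from insulin-reactive CD4 T cells, or TRAV5-4 rested on TRAV5-4 alone, which made up 6.79% and 6.90%. TRAV/DV segments made up 6.05% and 6.25%, TRAJ58 to TRAJ40 41.9% and 41.6%, TRAJ20 to TRAJ2 19.8% and 18.0%, the TRBJ1 cluster 32.8% and 32.1%, and the TRBJ2 cluster 67.2% and 67.9%.

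Receptors pairing the TRAV16 family with TRAJ42, known from CD8 T cells that recognise the islet antigen IGRP, did not pass the test among clonotypes (adjusted p = 0.995 by edgeR), and their share of cells did not overlap between genotypes. They made up 0.807% and 0.768% of NOD clonotypes and 0.890% and 0.705% of Tet2KO NOD clonotypes. Counted by cells, they made up 2.89% and 3.84% in NOD and 0.810% and 1.94% in Tet2KO NOD, a difference of -1.99 points (n = 2, exact permutation p = 0.333, the smallest possible). By cells 5 of the 13 lists did not overlap (38.5%, against 33.3% by chance). The other 4 were TRAJ58 to TRAJ40 (45.8% in NOD and 40.7% in Tet2KO NOD), TRAJ20 to TRAJ2 (19.2% and 18.0%), TRBV19 (9.89% and 7.32%) and TRBV2 (4.94% and 3.92%). Of the TRAV16-TRAJ42 clonotypes 44.8% and 69.2% in NOD and 37.5% and 71.4% in Tet2KO NOD had 2 or more cells, against 13.2%, 12.7%, 18.7% and 14.4% of the other clonotypes. The Wilson 95% interval lay above the other clonotypes in 3 of 4 libraries. The exception was Tet2KO NOD 1, with 8 such clonotypes (13.7% to 69.4%). The largest of them held 33, 34, 3 and 14 cells.

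Rearrangements of other T-cell types were few. Invariant NKT type receptors made up 11, 5, 3 and 5 clonotypes, each with 1 cell (0.306%, 0.295%, 0.334% and 0.504% of clonotypes). MAIT type receptors made up 1, 2, 0 and 2 clonotypes, and the 0 of 899 in Tet2KO NOD 1 allows a share of up to 0.334%. TRG or TRD contigs numbered 187, 51, 22 and 42, of which 144, 45, 15 and 30 were in called cells and 0 were productive. IG contigs numbered 0 in each library. The libraries were made for T-cell receptors, so the TRG, TRD and IG counts do not show how many cells with such receptors the islets held.

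The third comparison covered the CDR3 loops. Mean CDR3 beta length was 14.0 ± 0.0187 amino acids in NOD and 13.99 ± 0.0525 in Tet2KO NOD, and mean CDR3 alpha length was 13.66 ± 0.0177 and 13.65 ± 0.0299 (SD, n = 2, exact permutation p = 1 for both). Kyte-Doolittle hydropathy of CDR3 beta residues 6 and 7 averaged -1.159 ± 0.00292 and -1.213 ± 0.0347 (SD, n = 2, exact permutation p = 0.333). That difference of -0.0543 was -0.0298 without Tet2KO NOD 1 and turned to 0.0470 when each cell was counted once.

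The last comparison asked which receptors the libraries shared. Of 7143 distinct clonotypes, 34 occurred in over 1 library, 32 of them in 2 libraries and 2 in 3. Sharing followed the set number and not the genotype: NOD 1 and Tet2KO NOD 1 shared 15, and NOD 2 and Tet2KO NOD 2 shared 14, while the 2 NOD libraries shared 4 and the 2 Tet2KO NOD libraries 1. NOD 1 and Tet2KO NOD 2 shared 4, and NOD 2 and Tet2KO NOD 1 shared 0. Per 1000000 pairs of clonotypes the same-set values were 4.64 and 8.33, against at most 1.12 elsewhere. The shared clonotype with the most cells was the TRBV31 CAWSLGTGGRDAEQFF clone, with 41 cells in NOD 2 and 1 in Tet2KO NOD 2. The next were TRBV13-3 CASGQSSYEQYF with TRAV16N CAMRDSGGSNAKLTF (22 cells in NOD 2 and 2 in Tet2KO NOD 2) and TRBV16 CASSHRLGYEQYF with TRAV5-4 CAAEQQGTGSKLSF (22 in NOD 1 and 1 in Tet2KO NOD 1).

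CDR3 beta amino acid sequences, thinned to 899 clonotypes, were shared by a mean of 11.9 within genotypes and 14.4 between them (exact permutation p = 0.667 over the 3 splits). The same-set pairs shared 14.1 and 21.6, and the 2 Tet2KO NOD libraries also shared 14.1. Without clonotypes found in over 1 library the same-set pairs shared 9.46 and 15.6, and the difference within minus between genotypes moved from -2.46 to -0.32.

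**Figure D3:**
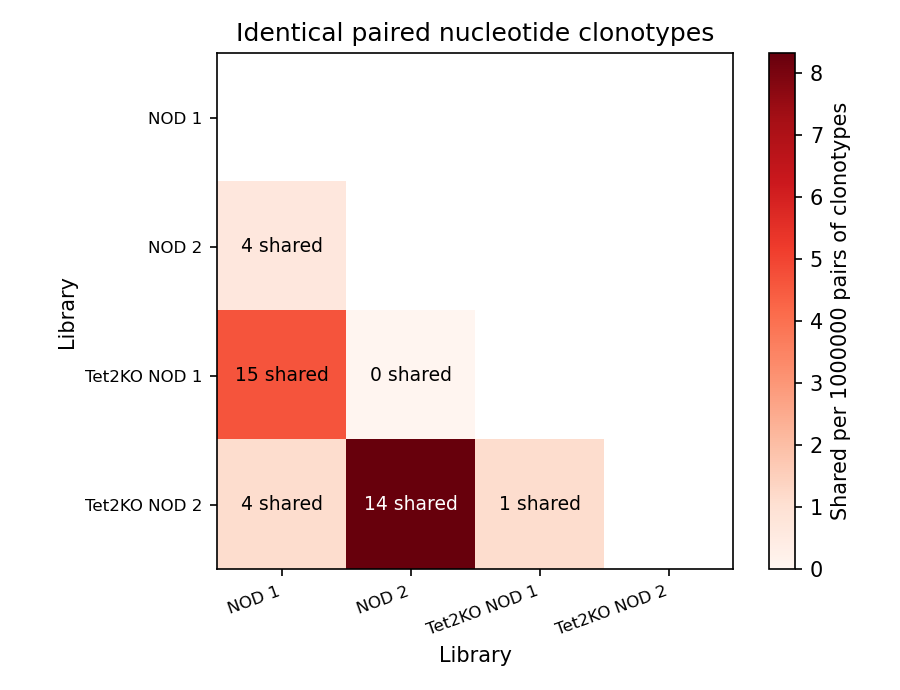
Identical paired nucleotide clonotypes for each pair of libraries (both axes), with the number shared printed in each square and the number per 1000000 pairs of clonotypes as colour. The squares of the same set hold 15 and 14, and the other 4 hold between 0 and 4.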

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

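The tests in this part were chosen after the results were seen. A signal stood out in contigs the comparisons do not use. Contigs named TRBV26 with no J segment and the sequence TGTAAAGGGAGGTTTTGTGAAGTT in place of a CDR3 (in 8573 of 8580; the rest had the same amino acids) made up 1.81% and 7.65% of NOD contigs and 26.2% and 25.8% of Tet2KO NOD contigs, a Tet2KO mean of 26.0%, with 0 in called cells. That sequence has 1 exact match in GRCm38, on chromosome 19 from 5802350 to 5802373 (minus strand), inside an exon of Malat1, an abundant nuclear non-coding RNA, and of Gm37376 on the other strand, not at TRBV26 on chromosome 6. Deeper sequencing of the Tet2KO libraries stays open, since the values go both ways. Their contigs held 0.552 times the NOD reads, 114106599 and 85137263 against 220516119 and 140478435, which goes against it. The median reads of such contigs were higher, however, at 50 and 37 in Tet2KO NOD against 35 and 33 in NOD. Reads in the contigs of called cells were 50021 per called cell in Tet2KO NOD against 36328. That measure does not cover such contigs, since 0 were in called cells. The gap per called cell rested largely on NOD 1, at 27650. NOD 2 and Tet2KO NOD 2 were close, at 45005 and 46412 reads per called cell, with 7.65% and 25.8% of such contigs. Tet2KO NOD 1 had 53630. Fewer T cells among the captured cells may account for the larger share of such contigs and could not be excluded. Barcodes with such contigs numbered 551, 1128, 3515 and 3378 in NOD 1, NOD 2, Tet2KO NOD 1 and Tet2KO NOD 2. Per called T cell there were 1.796 and 2.03 in Tet2KO NOD 1 and 2 (mean 1.91) and 0.0806 and 0.390 in NOD 1 and 2. That ratio rises by itself where called T cells are fewer, so it does not decide. The number of cells loaded was not analysed here. No biological explanation was tested.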

How the results depend on the processing

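The alternatives that left out clonotypes in over 1 library, merged names, crossed the sets or left out cells by contigs of any barcode were chosen after the data were seen; the planned filter on barcodes shared between libraries was run among called cells, and its wider forms moved the expanded share to 10.0 points (any contig) and 12.7 points (more reads). Values are Tet2KO NOD minus NOD. With 2 pools of each genotype no permutation p could pass 0.05, so for those values the direction is all that can hold. The expanded share and the number of clonotypes kept their direction in all alternatives run, the former between 5.73 and 19.7 points when each library was left out and 4.52 points without thinning, where the genotypes overlapped. Without thinning entropy was -0.0137 and inverse Simpson -271. Of values that answer a comparison, 124 kept direction and side of the threshold, 18 lost a call and 15 reversed; of single segments and lists, 485, 12 and 62. Where nothing else is said, the cause was not tested. Rare lists rested on few clonotypes. In the simulations 19.6% of segments changed 1.5-fold were recovered, and what limited this was not tested.

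The count of changed segments, 1, was 0 with DESeq2, with cells with over 1 TRB kept, with unpaired chains, with at least 2 UMIs, without clonotypes in over 1 library, with no filter (146 segments tested), with each cell once and with the replicate block, and 0 to 1 when each library was left out. The count of changed lists, 1, was 0 with cells with over 1 TRB kept and with each cell once, and 0 to 1 when each library was left out. The sets share only a number in the labels; deviations of same-set libraries correlated at -0.167, and with the crossed replicate block 0 segments and 0 lists passed.

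Within set 1 of the replicate block, reversed values were 0.0255 (CDR3 alpha length) and -0.0278 (MAIT type list). Within set 2 of the replicate block they were -2.55 (10 largest), -0.0761 (largest clonotype), 0.000741 (entropy), 73.0 (inverse Simpson), 0.0094 (CDR3 beta length), and for lists -0.0629 (TRAV16-TRAJ42), -0.608 (TRAV5-4), -0.101 (TRAV/DV), 1.26 (TRBJ1) and -1.26 (TRBJ2). With the replicate block in edgeR, log2 fold changes reversed to 0.0255 for TRBV12-2+TRBV13-2 and 0.0578 for TRAJ18, and with the crossed replicate block to 0.0022 for TRBV12-2+TRBV13-2 and -0.0014 for TRBJ2-5.

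The largest clonotype reversed to -0.164 with TRB alone and with the deposited clonotype numbers; the largest clone then also grew in NOD 2 and Tet2KO NOD 1. With each cell once, values reversed to 0.0152 (CDR3 beta length), 0.0470 (hydropathy), -1.99 (TRAV16-TRAJ42), 1.07 (TRBJ1) and -1.07 (TRBJ2), and log2 fold changes to 0.0087 (TRBV5), -0.0319 (TRBV16), -0.488 (TRAV16N) and -0.0507 (TRBJ2-3), since large clones then count by size. With any TRA of a cell allowed, the TRAV16-TRAJ42 list was -0.0404. With over 1 TRB kept, reversed values were 0.0027 (CDR3 alpha length), -0.0098 (TRAV16-TRAJ42), -0.0466 (TRAV/DV) and 0.0011 (TRAJ18). With at least 2 UMIs the TRAV16-TRAJ42 list was -0.0502. With unpaired chains, log2 fold changes were -0.0143 (TRAV5-4), -0.0511 (TRBJ2-5), 0.0128 (TRBJ2-1) and 0.0172 (TRAJ18). With TMM, TRBJ2-5 was -0.0054. With DESeq2, TRBV12-2+TRBV13-2 was 0.0082 and TRAJ18 0.0143.

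Leaving out each library gave ranges that crossed 0 for the 10 largest clonotypes (-0.657 to 6.41), CDR3 alpha length (-0.0293 to 0.0130), CDR3 beta length (-0.0516 to 0.0226) and the lists TRAJ58 to TRAJ40 (-0.958 to 0.223), TRAV/DV (-0.0064 to 0.403), MAIT type (-0.0730 to 0.128), TRAV16-TRAJ42 (-0.0824 to 0.102), TRAV5-4 (-0.549 to 0.771), TRBJ1 (-2.28 to 0.689), TRBJ2 (-0.689 to 2.28), TRBV19 (-1.97 to 0.351) and TRBV26 (-0.0087 to 0.331). The log2 ranges were TRAJ18 -0.50 to 0.38, TRAJ23 -0.0318 to 0.24, TRAV13-1 -0.23 to 0.0452, TRAV16N -0.0816 to 0.25, TRAV5-4 -0.12 to 0.16, TRAV6D-6 -0.22 to 0.10, TRAV6N-7 -0.0281 to 0.31, TRAV9-1 -0.37 to 0.35, TRBJ2-1 -0.23 to 0.0878, TRBJ2-5 -0.12 to 0.14, TRBV1 -0.14 to 0.27, TRBV12-2+TRBV13-2 -0.14 to 0.14, TRBV19 -0.30 to 0.0695 and TRBV5 -0.14 to 0.0310. A genotype left with 1 library was assumed to vary like the other.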

Other observations

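The tests in this part were chosen after the results were seen, except the UMI test of free RNA, whose bound was written first. Beyond identical clonotypes, nearly identical receptors recurred across libraries. Grouping clonotypes with the same segments and CDR3 lengths and at most 1 amino acid difference in each CDR3 gave 136 groups, 106 of them in over 1 library, 81 in both genotypes and 4 in all 4 libraries. The widest paired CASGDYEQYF (TRBV12-2+TRBV13-2, TRBJ2-7) with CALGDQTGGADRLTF (TRAV6D-6, TRAJ45): 11 nucleotide clonotypes with 1 amino acid sequence of each chain, in 39, 12, 1 and 4 cells of NOD 1, NOD 2, Tet2KO NOD 1 and Tet2KO NOD 2. The others in 4 libraries were led by TRBV5 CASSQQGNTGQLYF with TRAV5-4 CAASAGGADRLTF (16 cells), TRBV13-3 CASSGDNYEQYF with TRAV16N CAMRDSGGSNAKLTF (14 cells, a TRAV16-TRAJ42 pairing) and TRBV19 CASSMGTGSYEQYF with TRAV5-4 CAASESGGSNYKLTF (12 cells). These groups were named after their values were seen.

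Without clonotypes found in over 1 library, 78 groups lay in over 1 library and held 5.86%, 5.49%, 5.61% and 6.75% of cells, in the same order of libraries. Of their clonotypes 54.1%, 45.5%, 72.4% and 40.4% had 2 or more cells, against 12.4%, 11.7%, 17.1% and 12.9% of the others, higher in each of the 4 libraries (n = 4, exact paired permutation p = 0.125, the smallest possible). Independent pairing of common chains is argued against, since 100 shuffles of TRA among the clonotypes of each library gave at most 2 groups in over 1 library. Cells carried between the 2 libraries of a set cannot account for the 57 of the 106 groups (53.8%) that spanned both sets, and stay open for part of the others. A candidate explanation is that common antigens select them in both genotypes, which these data do not test.

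Identical nucleotide clonotypes were shared mostly within sets: 29 of 38 sharing events (76.3%) fell in same-set pairs, which hold 28.9% of the possible pairs of clonotypes. Equal chance recombination in all pairs is argued against (exact binomial p = 2.05e-09, over clonotypes and not pools). Cells on the side with fewer cells had 1.36 times the median TRB UMIs of their library (95% bootstrap interval 0.90 to 1.64, 29 cells). This argues against free RNA only for cells that passed the cell call and the chain filters, which may already have removed barcodes with few UMIs. Index hopping was first tested by asking whether a shared cell's barcode and TRB also occurred in the partner library; 24.6% did, which did not decide, because that counts cells whose own reads had leaked out. A second test asked for more reads in the partner, as a hopped cell needs, and 0 of 264 cells (0%) had them. Cells carried between pools of a set may account for the sharing but stay open. In the NOD libraries the shared clonotypes averaged 7.03 cells, above random clonotypes (median of draws 1.34, upper end of the 95% range 2.90). They also lay above recurring clonotypes found in 1 library (3.17, upper end 6.31). Without the largest of them the shared clonotypes averaged 5.82, inside the latter range. The draws kept their own largest clonotypes, so that last comparison is not like for like and does not decide.

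Traces of called cells occurred in every other library. Between 3.02% and 28.2% of the paired cells of a library had their barcode and TRB in a contig of a given other library, with a median of 0.0872% to 0.199% of their reads there. Same-set and other pairs averaged 17.2% and 17.7% of cells. Of all these, 1 cell had more reads in the other library.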
